A study of Mus musculus with 12 samples.

How the data were processed

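RNA was measured in 12 libraries of microglia from adult male C57BL/6N mice at postnatal day 60, with 3 libraries for each of 4 brain regions: cortex, hippocampus, striatum and cerebellum. Per the labels' protocols, tissue of a region was pooled from 3 to 5 mice, cells were kept on ice through douncing and myelin removal, and 3000 live cells of the TMEM119+ gate (CD45 low, CD11b+) were sorted per sample. Total RNA was copied with the Smart-Seq v4 kit, which primes on poly(A) tails and does not mark the strand. The cDNA was amplified for 9 cycles, 380 pg of it went into Nextera XT libraries amplified for 13 cycles, and the samples were barcoded and sequenced in a shared pool on a NextSeq. The labels do not state that the pools of a region came from separate mice, so p-values measure the spread between these libraries, which may be technical.

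The deposited table holds whole-number read counts per gene, without normalization, for 23337 gene symbols and no gene identifiers. Per the submitters' processing notes, the authors used Trim Galore 0.4.3, STAR 2.5.3a, Picard and HTSeq with the mm10 build. The roles of these tools, the annotation and the strand setting of the counting are not given in the sources used here. Because the kit does not mark strand, reads of overlapping genes on opposite strands cannot be told apart, and genes with near-identical copies (such as Hspa1a and Hspa1b, or ribosomal protein genes and their pseudogenes) are uncertain. The number of genes above 0 in each column equalled the detected-gene number in that sample's label in all 12 libraries. None of the 13 mitochondrially encoded genes of the list fixed for them was among the symbols, and that list was not analysed here.

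Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by region (minimum count 10, minimum total count 15), which left 12217 genes. Library sizes were scaled by TMM, and a negative binomial model with a mean for each region was fitted to all 12 libraries, so that the regions shared an estimate of the spread. The robust quasi-likelihood test (glmQLFit, glmQLFTest) was applied to the 6 pairs of regions, to cerebellum against the mean of the other 3 regions, and to the 4 regions together. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with a threshold of 0.05. Log2 fold changes carry the standard error of the quasi-likelihood fit. Expression levels are CPM values from edgeR with TMM-scaled library sizes, given as mean ± SD of 3 libraries. A fold against a region with no count in its libraries was computed against a floor of 3 counts over that region and is a lower bound.

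Similarity of regions was tested by the mean Pearson correlation of log2 CPM (prior count 2) within regions minus that between regions, with an exact one-sided permutation test over all groupings of the libraries. The 30 gene lists and the comparisons were fixed before the data were examined. They cover homeostatic, disease-associated, interferon, antigen presentation, immediate early, cytokine, phagocytosis, complement, lysosome, energy metabolism, ribosomal protein, cell cycle, clock, lipid and sex-linked genes, and markers of 12 other groups of cells. The 26 lists with at least 3 tested genes entered camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over all 182 tests. Camera with an estimated correlation and fry were alternatives. Adjustment over the list alone was also computed for each list and comparison. It makes no allowance for the number of lists and comparisons, so some such passes would arise by chance.

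The genes named were set by rule before the data were examined: for each pair, the 6 genes raised most and the 6 lowered most among those past the threshold with libraries that do not overlap (15 and 15 for cerebellum against the mean), or, where none passed, the 3 with the smallest p. From each list, up to 4 members with the smallest p over the 4 regions were taken, and Tmem119, P2ry12, Cx3cr1, Csf1r, Apoe, Xist and Ddx3y always. Predicted genes, RIKEN clones and ribosomal protein genes were left out of the rule for pairs. Other members are named where a statement needed them, chosen after their values were seen. Some genes that the rule names are not reported here.

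Total counts ran from 6479839 in striatum 2 to 14833340 in cortex 2. A count of 0 allows up to 3 counts, or 0.463 CPM in the smallest library. Reads without molecular identifiers are not independent molecules, so such floors cover counting error only. Between same-region libraries, the counts differed by far more than sampling noise in all 12 pairs (chi-square per degree of freedom 32.5 to 93.3), so no library was counted as a copy of another. The fits were tested on simulated counts for the 12217 genes with 200 genes changed between cerebellum and cortex, drawn 3 times from the measured means, library sizes and dispersions. In that simulation edgeR called 4.0% of genes changed 2-fold, 37.3% of those changed 4-fold and 64.1% of those changed 8-fold, and among genes with a mean of at least 200 counts 6.1%, 58.1% and 90.0%. DESeq2 called 18.9%, 58.7% and 75.8% of the genes changed 2-, 4- and 8-fold. Among the unchanged genes of that comparison, edgeR called 3.3 per draw, DESeq2 39.0 and limma-voom 0.7. In simulated hippocampus and cortex, where no gene was changed, DESeq2 called 16 to 20 genes and edgeR 0.

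Alternatives were relative log expression size factors, no count filter, a filter at a mean of 50 counts, DESeq2 1.42.0, limma-voom with sample quality weights, fits on the compared regions only, the replicate number as a block, counts thinned to the smallest total, and leaving out each library. A correction for transcript length was chosen after seeing the data: each library's smooth trend of expression with the length of the longest transcript (lowess span 0.3) was removed as an offset. Lengths and gene positions came from GENCODE vM21 on GRCm38, the assembly also called mm10, by gene symbol. Symbols or older symbols matched for 97.9% of the table and 98.7% of the tested genes.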

Results

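Microglia, the resident macrophages of the brain, were profiled by bulk RNA sequencing to compare the homeostatic state of these cells between 4 regions of the adult mouse brain. The 12 libraries comprised 3 each from cortex, hippocampus, striatum and cerebellum, each made from 3000 cells of the TMEM119+ gate. Total counts ranged from 6479839 in striatum 2 to 14833340 in cortex 2. Between 12214 and 13614 genes had at least 1 count in 11 of the libraries, and 10929 in striatum 2. After the filter on low counts, 12217 genes were compared.

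All 4 regions expressed the homeostatic microglia genes at high levels. Tmem119, the gene of the sorted surface marker (chromosome 5, 113793729 to 113800516, GRCm38), stood at 2016 ± 635 CPM in cortex, 1933 ± 211 in hippocampus, 1733 ± 408 in striatum and 2122 ± 1082 in cerebellum (SD, n = 3 each). P2ry12, a purinergic receptor of ramified microglia, ranged from 4183 ± 104 CPM in cortex to 5096 ± 1140 in cerebellum. The fractalkine receptor gene Cx3cr1 ranged from 2766 ± 886 CPM in cortex to 3157 ± 571 in hippocampus. Csf1r, the receptor that microglia need to survive, had means of 6928 ± 1134 CPM in cortex, 7822 ± 474 in hippocampus, 8648 ± 966 in cerebellum and 9554 ± 1230 in striatum. None of these 4 genes passed the 4-region test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.00 each). Against cortex, the log2 difference of Csf1r was 0.46 in striatum (95% interval 0.14 to 0.78) and 0.32 in cerebellum (0.00 to 0.64), and that of P2ry12 in cerebellum was 0.29 (−0.08 to 0.65).

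**Figure D1:**
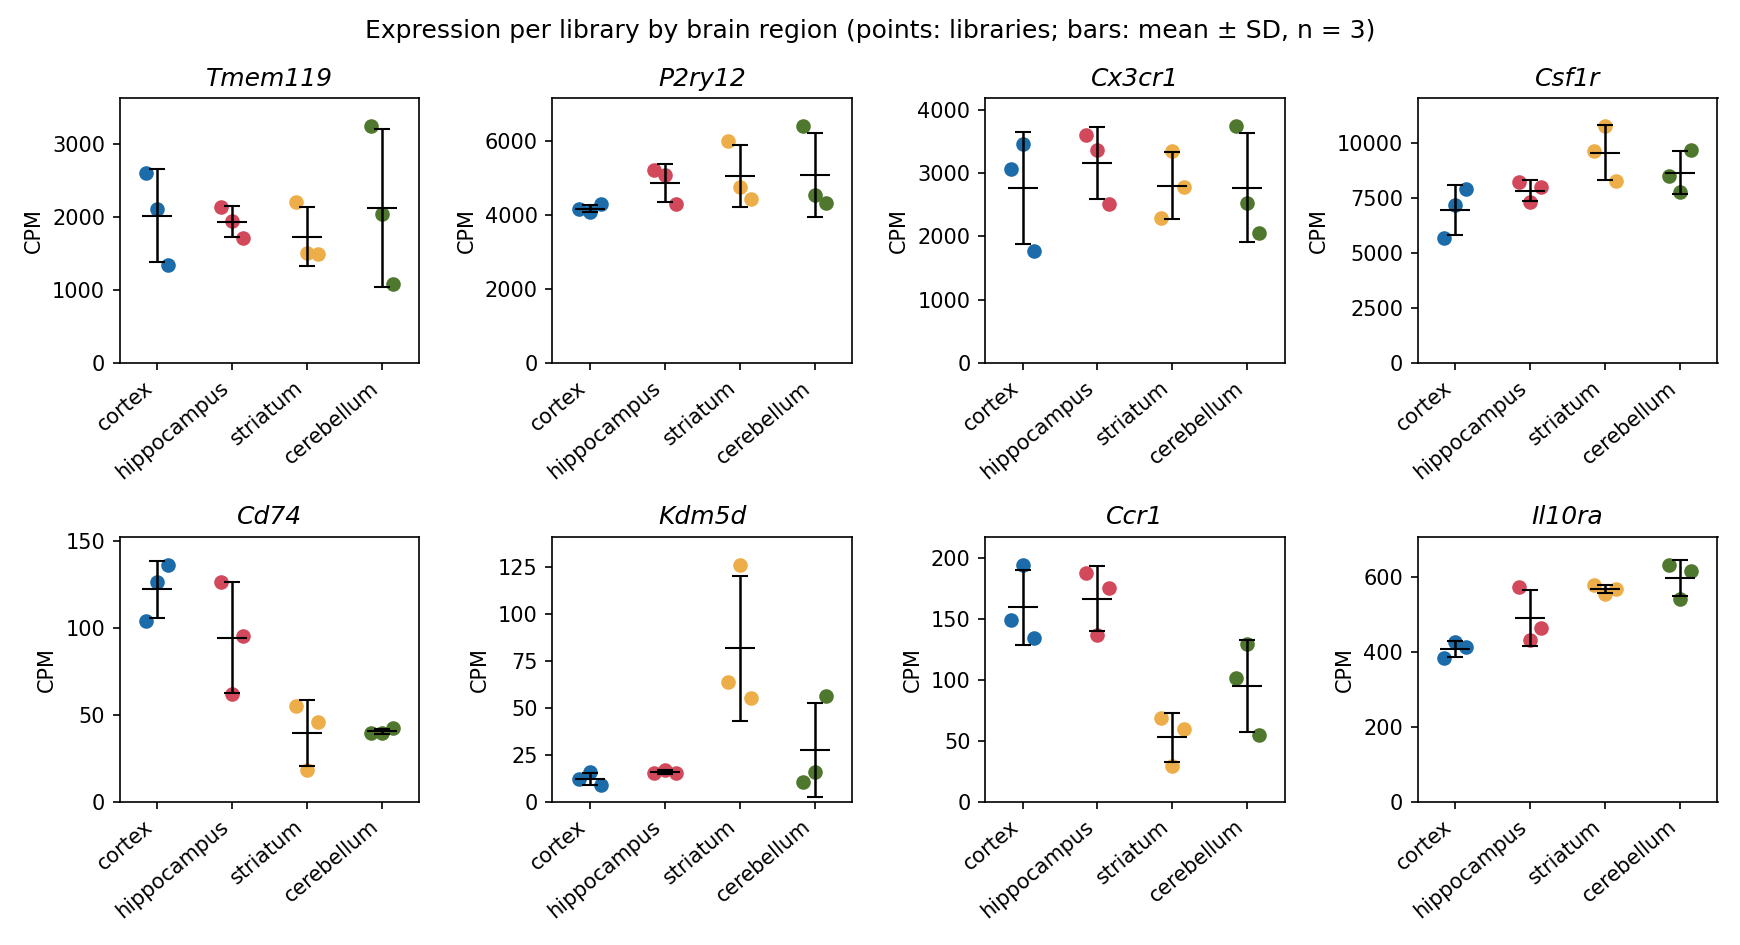
Normalised expression (CPM, linear axes from 0) of 8 genes in the 3 libraries of each region; points are libraries and bars are mean ± SD. Cd74 lay at 39.8 to 42.3 CPM in the cerebellum libraries and at 104 to 136 CPM in the cortex libraries, while the ranges of Tmem119 overlapped between all regions.

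Libraries of a region did not resemble each other more than libraries of different regions. The mean Pearson correlation of log2 CPM was 0.8816 within regions and 0.8842 between them, a difference of −0.0026 (exact permutation test over all groupings of the libraries, one-sided, p = 0.812). The sign of this difference turned with the replicate number as a block (0.0092, exact p = 0.11) and without striatum 1 (0.0105, exact p = 0.161) or striatum 3 (0.0120, exact p = 0.136). Removing the means of the replicate numbers lowers the correlation of same-numbered libraries, which all come from different regions, so that rise is built in. Leaving out striatum 1 or striatum 3 removes a low within-region pair with striatum 2 (r = 0.755 and 0.771) and keeps the low between-region pairs of striatum 2. None of these turns shows that regions separate. Striatum 2 correlated with the other 11 libraries at 0.748 to 0.771, whereas those 11 correlated with each other at 0.858 to 0.936. In striatum 2, 986 of the 10018 genes with a mean of at least 50 counts had no count (9.84%), against 4 to 44 of these genes in each of the other libraries. The first principal component, 46.6% of the variance, separated this library from the rest.

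**Figure D2:**
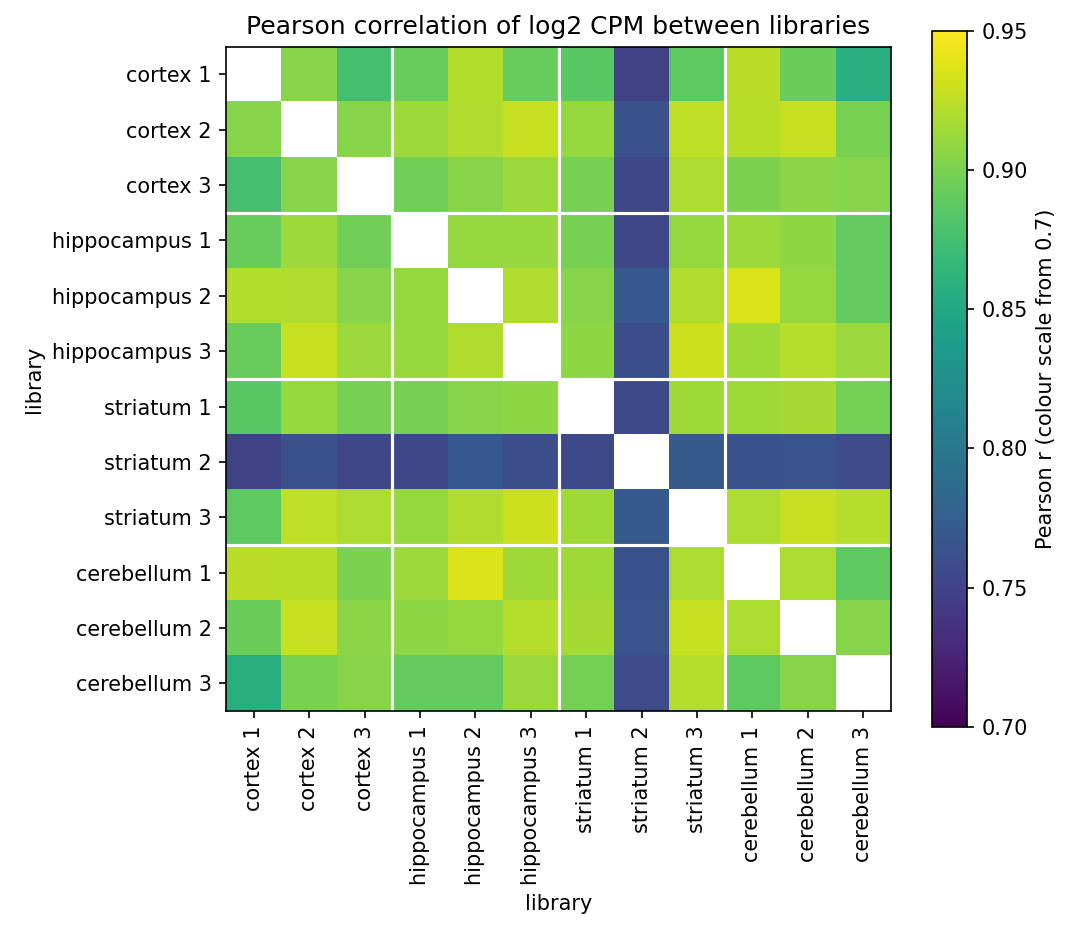
Pearson correlation of log2 CPM over 12217 genes for every pair of the 12 libraries; white lines part the regions and the diagonal is blank. The row of striatum 2 stands apart at 0.748 to 0.771, and no block of a region stands out from its surroundings.

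Over the 4 regions, the genes of the lists fixed in advance with the smallest p were Kdm5d (F = 10.59) and Cd74 (F = 10.24). Cd74, the invariant chain of MHC class II (chromosome 18, 60803848 to 60812652, GRCm38), was at 122 ± 16.5 CPM in cortex and 94.4 ± 32.1 in hippocampus, and at 39.7 ± 19.0 in striatum and 40.7 ± 1.41 in cerebellum (SD, n = 3 each). Among the 6 tested class II genes, Cd74 alone passed when adjusted over the list alone (edgeR, adjusted p = 0.00636). The class II genes H2-Ab1, H2-DMa and H2-DMb1 did not pass, at 9.04 to 15.2, 63.7 to 88.6 and 37.28 to 49.97 CPM. Kdm5d and Ddx3y, Y-linked genes for a histone demethylase and an RNA helicase, passed as well when adjusted over their list alone (edgeR, adjusted p = 0.00366 and 0.0395 among 4 genes). Kdm5d was at 81.5 ± 38.6 CPM in striatum, 12.2 ± 3.36 in cortex, 15.8 ± 0.873 in hippocampus and 27.5 ± 24.9 in cerebellum, where 1 library held 56.1 CPM and the others 10.7 and 15.8. Ddx3y was at 158 ± 48.9 CPM in striatum and 74.3 ± 14.5 in cortex. The 2 other Y-linked genes, Eif2s3y and Uty, did not pass (132 ± 62.9 and 22.7 ± 19.6 CPM in striatum, 85.4 ± 18.5 and 32.3 ± 22.4 in cortex). Xist had 0 counts in all 12 libraries, which allows up to 0.463 CPM in the smallest. Adjusted over all 12217 genes, no gene passed (edgeR, 0 genes; 222 genes at an unadjusted p under 0.05, where chance alone gives about 611). A number below the chance level does not show that regions are alike, and limma-voom gave 539 such genes. DESeq2 called 5 genes over the 4 regions, among them Ccr1, Cd74, Fbxl8 and Kdm5d, and limma-voom called 0. Ddx3y lost its list-alone call in limma-voom, with the replicate number as a block, with the length correction and without any of cortex 1, cortex 2, cerebellum 1, hippocampus 2, hippocampus 3, striatum 2 and striatum 3, whereas Cd74 and Kdm5d kept theirs in all 12 fits that left out a library.

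Between cerebellum and cortex, Cd74 was lower in cerebellum by a log2 difference of −1.59 (SE 0.36, 95% interval −2.38 to −0.80), with all 3 cerebellum libraries below all 3 cortex libraries. The libraries of these regions did not overlap, in either direction, for 825 of the 12217 genes (6.8%), where chance alone gives 10%. Il10ra, the ligand-binding chain of the interleukin 10 receptor, was at 598 ± 47.8 CPM in cerebellum and 407.8 ± 21.01 in cortex (log2 difference 0.55, SE 0.15). Fbxl8, an F-box gene, was at 7.43 ± 3.46 CPM in cerebellum and 0.161 ± 0.225 in cortex (log2 difference 5.53, SE 1.14; 4.94 without cortex 1 and 7.35 without cortex 3). These had the smallest p of the comparison and did not pass (edgeR, adjusted p = 1.00 each; 0 genes of 12217, 189 at an unadjusted p under 0.05). DESeq2 called 7 genes and limma-voom 0. Among the lists, 22 of 25 homeostatic genes lay above their cortex level (median log2 difference 0.18; camera adjusted p = 0.000692). All 34 ribosomal protein genes and 35 of 36 nuclear oxidative phosphorylation genes lay below it (medians −0.34 and −0.31, adjusted p = 7.29e-09 and 4.18e-07). Of 17 glycolysis genes 14 lay below (median −0.35, adjusted p = 0.000109), for example Gapdh at 271 ± 16.0 against 371 ± 45.1 CPM. Of 21 immediate early and stress genes 17 lay below (median −0.36, adjusted p = 0.00186), for example Egr1 at 7.01 ± 3.56 against 24.8 ± 10.2 CPM. Cell cycle genes (15 of 21 below, median −0.23, adjusted p = 0.00357) included Mcm3 at 274 ± 45.0 against 424 ± 8.17 CPM, and lipid and cholesterol genes (15 of 20 below, median −0.34, adjusted p = 0.0193) included Sqle at 26.7 ± 14.2 against 80.5 ± 42.8 CPM. Under camera's estimated correlation these 7 list calls ended (adjusted p = 0.73 for the glycolysis and immediate early lists, 0.81 for the other 5). Without cortex 1 the ribosomal and oxidative phosphorylation calls ended (adjusted p = 0.286 and 0.244), the second also without cerebellum 3, and of the 12 fits that left out a library the homeostatic, cell cycle and lipid calls each held in 10, while the glycolysis and immediate early calls held in all 12 (highest adjusted p = 0.007 and, just below the threshold, 0.05).

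Between hippocampus and cortex, all 26 lysosomal genes lay higher in hippocampus (median log2 difference 0.19; camera adjusted p = 3.7e-06), for example Glb1, the lysosomal beta-galactosidase, at 140 ± 1.83 against 102.1 ± 13.1 CPM. The libraries overlapped in the mean of this list, as log2 deviation from all libraries. It was −0.17, −0.30 and 0.11 in cortex 1, 2 and 3, and 0.01, 0.26 and 0.07 in hippocampus 1, 2 and 3. These genes also varied together within regions (median correlation 0.26), so they are not independent results. Of 25 homeostatic genes 17 lay higher (median 0.11, adjusted p = 0.0456), and 16 of 25 phagocytosis and clearance receptor genes did (median 0.16, adjusted p = 0.0427). Of 34 ribosomal protein genes 33 lay lower (median −0.27, adjusted p = 0.000621), as did 31 of 36 oxidative phosphorylation genes (median −0.14, adjusted p = 0.0449). With an estimated correlation the adjusted p was 0.81 for the first 3 lists, 0.84 for the ribosomal list and 0.88 for the oxidative phosphorylation list. Of the 12 fits that left out a library, the lysosomal call held in all 12 (highest adjusted p = 0.048), the homeostatic in 5, the phagocytosis in 3, the oxidative phosphorylation in 5 and the ribosomal in 10, and without cortex 1 the adjusted p of the last 2 was 0.208 and 0.404. The correction for transcript length ended the same calls, with adjusted p = 0.699 for oxidative phosphorylation and 0.0547 for ribosomal proteins. No single gene passed (edgeR, 0 genes; 124 at an unadjusted p under 0.05; smallest adjusted p = 1.00). Among the genes with the smallest p, Fbxl8 was at 4.65 ± 1.82 CPM in hippocampus and 0.161 ± 0.225 in cortex (log2 difference 4.85; 4.26 without cortex 1 and 6.67 without cortex 3), and Eid3 was at 2.42 ± 1.36 CPM in hippocampus with no count in cortex, at least 30.8-fold higher. DESeq2 called 5 genes, all higher in hippocampus, and limma-voom 0.

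Between striatum and cortex, Ccr1, a chemokine receptor, was at 52.9 ± 20.5 CPM in striatum and 159.7 ± 30.99 in cortex (log2 difference −1.59, SE 0.35). Kdm5d (log2 difference 2.74, SE 0.55) and Brox (229 ± 93.1 against 95.3 ± 17.6 CPM; log2 difference 1.26, SE 0.27) lay higher. These 3 had the smallest p and did not pass (edgeR, adjusted p = 0.80 each; 0 genes, 683 at an unadjusted p under 0.05). Cd74 differed by −1.62 (SE 0.36; edgeR adjusted p = 0.80 over all genes and 0.00505 when adjusted over the list alone). DESeq2 called 13 genes, 10 higher and 3 lower, and limma-voom 0. Among lists, homeostatic genes (19 of 25 higher, median 0.18, camera adjusted p = 0.00357) and lysosomal genes (23 of 26 higher, median 0.18, adjusted p = 0.00379) lay higher in striatum. Ribosomal protein (34 of 34 lower, median −0.48, adjusted p = 6.6e-06), oxidative phosphorylation (35 of 36 lower, median −0.34, adjusted p = 0.00218) and glycolysis genes (15 of 17 lower, median −0.30, adjusted p = 0.0427) lay lower. The sex-linked list passed as well (3 of 4 higher, adjusted p = 0.00279). All 6 tested choroid plexus and ependymal markers were higher (adjusted p = 0.00435), among them transthyretin, Ttr, at 580 CPM in striatum 2 and 35.2 and 87.2 CPM in the other striatum libraries. When the correlation was estimated, the adjusted p was 0.73 for the sex-linked list, 0.81 for the homeostatic, lysosomal, glycolysis and choroid plexus lists, 0.82 for the ribosomal list and 0.84 for oxidative phosphorylation. Without striatum 2 the homeostatic, lysosomal and choroid plexus calls ended (adjusted p = 0.0659, 0.0826 and 0.163), and without cortex 1 the oxidative phosphorylation, glycolysis and ribosomal calls (0.521, 0.0764 and 0.136), whereas the sex-linked call held in all 12 fits that left out a library. Other libraries ended calls too: over the 12 fits the glycolysis call held in 6, the homeostatic in 9, the lysosomal and oxidative phosphorylation in 10, and the ribosomal and choroid plexus in 11. After the length correction the oxidative phosphorylation and glycolysis calls ended (adjusted p = 0.635 and 0.0614).

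Between striatum and hippocampus, Ccr1 (log2 difference −1.65, SE 0.35) and Wdr75 (20.8 ± 8.69 against 59.4 ± 15.3 CPM; −1.51, SE 0.35) were lower in striatum. Ulk1, a kinase that starts autophagy, was higher, with libraries from 66.6 to 148.6 CPM in striatum against 34.4 ± 13.8 CPM in hippocampus (log2 difference 1.58, SE 0.37). These 3 had the smallest p and did not pass (edgeR, adjusted p = 0.95 each; 0 genes, 530 at an unadjusted p under 0.05; DESeq2 0 and limma-voom 0). Ribosomal protein genes (32 of 34 lower, median −0.24, camera adjusted p = 0.0368) and 10 of 10 neuronal markers (adjusted p = 0.0148) lay lower in striatum. The 6 choroid plexus and ependymal markers (adjusted p = 0.00142) and 3 of 4 sex-linked genes (adjusted p = 0.00949) lay higher. With an estimated correlation the adjusted p was 0.88 for the ribosomal, 0.81 for the neuronal and choroid plexus, and 0.73 for the sex-linked list. The choroid plexus call ended without striatum 2 (adjusted p = 0.0735) and the sex-linked call without hippocampus 3 (0.056), and of the 12 fits that left out a library the ribosomal call held in 9 and the neuronal call in 10. The ribosomal call also ended with the length correction (adjusted p = 0.53). Of the neuronal markers, Snap25 was at 0.211 ± 0.366 CPM in striatum and 2.41 ± 1.49 in hippocampus, and Meg3 at 5.82 ± 4.75 and 9.25 ± 2.33 CPM.

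Between cerebellum and hippocampus, 21 of 24 disease-associated microglia genes lay lower in cerebellum (median log2 difference −0.24; camera adjusted p = 0.0011), for example Clec7a, the beta-glucan receptor, at 9.03 ± 8.05 against 37.0 ± 20.6 CPM. Of 12 markers of border-associated macrophages 8 lay lower as well (median −0.47), without passing camera (adjusted p = 0.117). Lower lists were also glycolysis (14 of 17, median −0.31, adjusted p = 0.00175), oxidative phosphorylation (33 of 36, −0.16, 0.00321), lysosome (21 of 26, −0.13, 0.00781), immediate early and stress genes (17 of 21, −0.20, 0.0148), lipid and cholesterol metabolism (15 of 20, −0.31, 0.0281), ribosomal proteins (29 of 34, −0.14, 0.0308) and cell cycle (13 of 21, −0.17, 0.0427). By camera with an estimated correlation, the adjusted p was 0.73 for glycolysis, 0.84 for oxidative phosphorylation, 0.88 for ribosomal proteins and 0.81 for the other 5 lists. None of these 8 calls held in all 12 fits that left out a library: glycolysis held in 11, the disease-associated and ribosomal lists in 9, lipid in 8, cell cycle in 5 and the others in 10. With the length correction the ribosomal call ended (adjusted p = 0.232). Abl1, a tyrosine kinase gene, was at 161 ± 21.7 CPM in cerebellum and 86.1 ± 23.6 in hippocampus (log2 difference 0.90, SE 0.24), and Ralgapa2 at 9.70 ± 7.35 against 0.241 ± 0.353 CPM (log2 difference 5.26; 4.60 without cerebellum 3 and 7.48 without hippocampus 2). Stx19 was at 1.53 ± 0.103 CPM with no count in hippocampus, at least 16.9-fold higher. Its mean in striatum was 3.18 ± 3.01 CPM, with a spread nearly as large as the mean, so no ranking of these 2 regions is drawn. These 3 did not pass (edgeR, adjusted p = 1.00; 0 genes, 156 at an unadjusted p under 0.05; DESeq2 2 genes, limma-voom 0). Cd74 passed only when adjusted over the list alone (edgeR, adjusted p = 0.0362).

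Between cerebellum and striatum, Wwc2 was at 13.5 ± 5.65 CPM in cerebellum and 56.0 ± 41.6 in striatum (log2 difference −2.05, SE 0.50), where striatum 2 held 103.6 CPM and the other libraries 26.7 and 37.8. Without striatum 2 the log2 difference was −1.26. Pkia, a protein kinase A inhibitor, had no count in cerebellum, and was at 83.1 CPM in striatum 2 but at 0.828 and 1.58 CPM in the other striatum libraries. Both were among the genes with the smallest p and did not pass (edgeR, adjusted p = 1.00; 0 genes, 293 at an unadjusted p under 0.05; DESeq2 3 genes, limma-voom 0). Lysosomal genes (18 of 26 lower, median −0.07, camera adjusted p = 0.0427), choroid plexus and ependymal markers (6 of 6 lower, adjusted p = 0.00655) and sex-linked genes (3 of 4 lower, adjusted p = 0.0335) lay lower in cerebellum, and all 3 calls ended without striatum 2 (adjusted p = 0.363, 0.379 and 0.103). Over the 12 fits that left out a library they held in 7, 10 and 7. With an estimated correlation the adjusted p was 0.84, 0.81 and 0.81.

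Cerebellum was also compared with the mean of the other 3 regions. The lists that lay lower in cerebellum were disease-associated microglia genes (19 of 24, median −0.14, camera adjusted p = 0.00287), oxidative phosphorylation (32 of 36, −0.16, 0.000621), glycolysis (13 of 17, −0.24, 0.00142), ribosomal proteins (31 of 34, −0.11, 0.00304), immediate early and stress genes (14 of 21, −0.20, 0.0111) and cell cycle genes (14 of 21, −0.15, 0.0388). With an estimated correlation their adjusted p ran from 0.73 to 0.84. Without cerebellum 3 the calls of the last 5 of these lists ended. Of the 12 fits that left out a library, the disease-associated call held in 7, the cell cycle in 6, the ribosomal in 9 and the others in 11. Beside the disease-associated genes, 10 of 12 markers of border-associated macrophages lay lower (median −0.34, camera adjusted p = 0.279). Creb3l4 (1.90 ± 0.681 CPM in cerebellum, no count in cortex or striatum, and in hippocampus only in hippocampus 3, at 0.855 CPM) lay higher in cerebellum, and Wwc2 lay lower (log2 difference −1.44, SE 0.41). Stx19 was at 1.53 ± 0.103 CPM in cerebellum and at 3.18 ± 3.01 in striatum, where the spread was nearly as large as the mean. These 3 did not pass (edgeR, adjusted p = 1.00; 0 genes, 131 at an unadjusted p under 0.05; DESeq2 2 genes, limma-voom 0). C5ar1, the receptor of complement fragment C5a, was at 132 ± 5.49 CPM in cerebellum and at 195 ± 47.0, 198 ± 41.1 and 229 ± 65.1 in cortex, hippocampus and striatum, and did not pass when adjusted over the list alone (edgeR, adjusted p = 0.0814). The intervals set a bound on what could differ: of the 7811 genes with a mean of at least 200 counts, 72.5% had a 95% interval within a 2-fold change here, and 42.5% to 54.6% in the 6 pairs.

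Of the 26 lists tested, 13 passed camera in no comparison. The interferon response list (27 genes, smallest adjusted p = 0.237) included Bst2 at 55.6 ± 22.2 to 87.4 ± 28.1 CPM and Rsad2 from 0.872 ± 1.37 CPM in striatum to 7.34 ± 3.84 in cerebellum. Stat2 of the same list was at 127.8 ± 47.9 CPM in striatum and at 65.1 ± 25.5 to 70.6 ± 17.8 CPM in the other regions, and did not pass the 4-region test (edgeR, unadjusted p = 0.0321, adjusted p = 1.00). MHC class I presentation (13 genes, 0.278), MHC class II presentation (6 genes, 0.0693), complement (10 genes, 0.265), the circadian clock (14 genes, 0.495) and cytokines, chemokines and NF-kB targets (22 genes, 0.42) did not pass either. Examples were Tap1 at 72.6 ± 36.0 to 109 ± 37.2 CPM, the chemokine gene Ccl12 at 116 ± 31.5 to 162 ± 35.3 CPM, and Clock at 20.5 ± 11.8 to 74.6 ± 54.1 CPM. In the 30 lists no member passed the 4-region test over all genes (edgeR, 0 genes), and 3 passed when adjusted over the list alone, Cd74, Kdm5d and Ddx3y. The adjustment over the list alone makes no allowance for the number of lists, so chance passes are possible among them.

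Markers of other cells, of which the TMEM119+ CD45low CD11b+ gate would leave few, were examined as well. None of the 12 cerebellar neuron markers was expressed enough to be tested, with Cbln1 and Gabra6 at 0 counts in all libraries, and 1 of the striatal neuron markers was, Ppp1r1b at 1.15 ± 1.61 to 1.79 ± 1.08 CPM. The smallest adjusted p of camera was 0.0927 for cortical and hippocampal excitatory neurons (5 tested, such as Prox1 at 2.30 ± 0.523 to 10.95 ± 7.15 CPM), 0.142 for astrocytes (9 tested, such as Aldoc at 1.11 ± 1.78 to 6.97 ± 4.26 CPM), 0.093 for the oligodendrocyte lineage (6 tested) and 0.0927 for monocytes and neutrophils (3 tested, such as Ccr2 at 0.593 ± 0.543 to 5.61 ± 1.86 CPM). It was 0.27 for endothelial cells (6 tested), 0.2 for lymphocytes (3 tested) and 0.117 for border-associated macrophages (12 tested). Kdr, an endothelial receptor gene, was at 5.32 ± 3.22 CPM in cerebellum and 0.0539 ± 0.0933 in striatum, and passed between these regions when adjusted over the list alone (edgeR, adjusted p = 0.0451), without allowance for the number of lists and comparisons. The mural and fibroblast list had 2 tested genes, of which Tagln was at 1.54 ± 1.39 to 8.17 ± 9.26 CPM. Stab1 and Dab2, border-associated macrophage markers that microglia also express, were at 532 ± 157 to 879 ± 505 and 272.8 ± 30.99 to 416 ± 84.4 CPM. Of the markers of these macrophages, 10 had a mean of at least 50 counts. The log2 mean of Lyve1, F13a1, Cd163 and Pf4, relative to the region's mean, ran from −3.33 in striatum 1 to 2.97 in cortex 3.

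Genes of the disease-associated state varied widely between libraries of the same region. Spp1, which encodes osteopontin, was at 21.4 and 23.02 CPM in cortex 2 and cortex 1 but 539 CPM in cortex 3, and at 29.8, 161 and 553 CPM in the hippocampus libraries. Apoe, the lipid carrier of activated microglia, ran from 2147 to 5459 CPM within cortex and from 3114 to 6026 CPM within hippocampus, with region means of 3498 ± 1738 (cortex), 4433 ± 1475 (hippocampus), 4873 ± 1224 (striatum) and 4360 ± 1556 CPM (cerebellum). It did not pass the 4-region test (edgeR, adjusted p = 1.00). In the region-centred log2 values, the median correlation between pairs of the 24 genes over the 12 libraries was 0.58, against a median of 0.01 and a highest value of 0.32 in 10000 random lists matched on expression. Other lists varied together as well, ribosomal proteins at 0.80 and oxidative phosphorylation at 0.75, which were 0.22 and 0.24 after the length correction, whereas the disease-associated list was then at 0.63. The mean of the list lay below its region's mean in all 4 libraries of replicate 1 (by log2 values from −0.85 to −0.29) and above it in all 4 of replicate 3 (0.09 to 1.09). The mean of the border-associated macrophage markers Lyve1, F13a1, Cd163 and Pf4 lay above its region's mean in replicate 3 as well (0.71 to 2.97), and ran from −3.33 to 0.56 in replicate 1. The correlation within the list is across genes and libraries of these samples, and genes are not independent replicates.

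**Figure D3:**
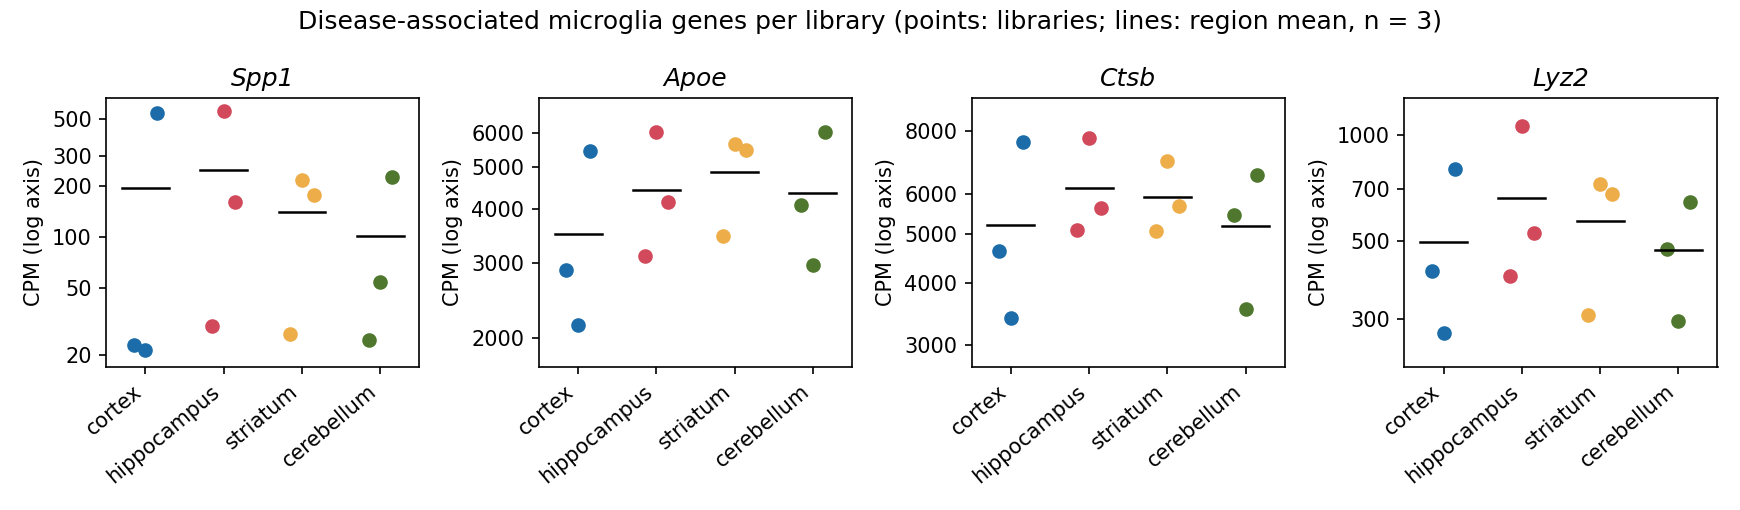
Normalised expression (CPM, log axes) of 4 disease-associated microglia genes in the 3 libraries of each region; points are libraries and lines are region means. Within cortex Spp1 spans 21.4 to 539 CPM and Lyz2 274 to 801 CPM, and the ranges of the regions overlap for all 4 genes.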

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

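The length-trend correction, alone or with striatum 2 left out, and the test of list-alone counts under each setting were chosen after seeing the data. The 8 counts of genes past the threshold, 0 each, stayed 0 with relative log expression factors, no count filter, the stricter filter, limma-voom, fits on the compared regions (the 6 pairs), thinned counts, the length correction and without each library (lowest 0, highest 0). The number of genes at an unadjusted p under 0.05 depended on the method. From edgeR to limma-voom it rose from 189 to 708 in cerebellum minus cortex and from 156 to 913 in cerebellum minus hippocampus. For cerebellum against the mean it rose from 131 to 821. It fell only in striatum minus cortex, from 683 to 559. The low edgeR numbers are therefore no evidence that regions are alike. DESeq2 called 5 genes over the 4 regions, 5 in hippocampus minus cortex, 13 in striatum minus cortex, 7 in cerebellum minus cortex, 2 in cerebellum minus hippocampus, 3 in cerebellum minus striatum and 2 in cerebellum against the mean. The cause was not tested. DESeq2 called 16 to 20 genes in simulated hippocampus and cortex where none was changed. That simulation gave more small p-values than the data, so it does not decide whether these calls are false. Of the named genes, no log2 fold change reversed, and 7 log2 fold changes and 5 of the 4-region values passed in DESeq2 alone. The difference between within-region and between-region correlation, −0.0026, turned positive with the replicate block (0.0092) and without striatum 1 (0.0105) or striatum 3 (0.0120), and ran from −0.0071 to 0.0120 (exact p 0.136 to 0.928) over the libraries left out. The block lowers the correlation of same-numbered libraries of different regions by construction. Without striatum 1 or striatum 3, a low within-region pair of striatum 2 is gone while its low between-region pairs stay. These turns therefore do not show that regions separate. Of 40 list tests past the threshold, 0 passed with an estimated correlation and 0 with fry. The first setting estimated the correlation between genes, otherwise preset at 0.01, and with it camera also tests on fewer degrees of freedom. These changes were not separated. Within regions the median correlation was 0.80 for ribosomal proteins, 0.75 for oxidative phosphorylation and 0.58 for disease-associated genes. It was 0.12 for glycolysis and 0.06 for immediate early genes. The preset p-values of the strongly correlated lists are therefore too small. Those of the glycolysis and immediate early lists are not thereby shown to be sound, and why their calls ended was not tested. For fry the cause was not tested, and fry compares no list with other genes. The list count ran from 31 to 49 without single libraries and was 40 after the length correction (34 shared; 6 calls ended, of ribosomal, oxidative phosphorylation and glycolysis lists) and 30 with striatum 2 also left out (24 shared). The 3 genes past the threshold over their list alone became 5 with the length correction and striatum 2 left out, and 2 to 4 without single libraries; the cause was not tested. The replicate numbers were not taken to pair the libraries: of 18 same-numbered pairs, 3 correlated above 0.1 in their deviations (−0.12 to 0.29), although 9 of 12 libraries correlated best with their own number. Replicate 3 was also lowest on the second principal component in every region (−62.2 to −18.7), whereas replicates 1 and 2 had no common order. A batch or pairing shared by number therefore stays open, and the main model leaves it out. With the replicate block, gene counts stayed 0, 45 list tests passed and 2 genes passed over their list alone. Alternatives planned for CPM, TPM, RPKM or FPKM were not run, since the values are counts. Depth limits genes near the floor, and at 3 libraries per region a 2-fold change of a gene was seldom called in the simulation of cerebellum and cortex (4.0%). That rate may not carry over to the measured libraries.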

Other observations

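The tests of glycolysis alone, the counts of other splits for gene counts, the run of the molecule model on the other libraries, the test of the replicate number and the length correction of another split were chosen only after the result was seen. In striatum 2, none of 25 homeostatic, 26 lysosomal, 36 oxidative phosphorylation and 34 ribosomal protein genes with a mean of at least 50 counts was at 0. Of the 986 genes at 0, 934 were among the 5009 less expressed genes, and the lists were not tested against genes matched on expression. Genes at 0 in this library but above 0 in the other 11 included Cry1, Cry2 and Dbp of the clock list, Fdft1 and Fasn of the lipid list, and C3 of the complement list, which was at 0.304 CPM in cortex 1. Choroid plexus genes had their highest levels in the same library, with Ttr at 580 CPM, Enpp2 at 158 and Kcnj13 at 40.3 CPM.

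A first pattern was the lower level of ribosomal protein, oxidative phosphorylation and glycolysis genes in cerebellum than in cortex. Glycolysis transcripts had a median of 3195 nt, near the 3328 nt of all genes, so the length correction had little to remove from this list. The list kept its mean log2 difference of −0.31 both after the length correction (−0.30) and without cortex 1 (−0.31). This argues against transcript length and against that library as the whole cause of the glycolysis difference in this comparison. The list mean, as log2 deviation from all libraries, was 0.24, 0.24 and 0.22 in cortex 1, 2 and 3. It was −0.17, 0.17 and −0.36 in cerebellum 1, 2 and 3, so cerebellum 2 lay near the cortex libraries. For the other lists, whose transcripts are short (median 1124 and 1186 nt, against 3328 nt for all genes), all 3 lists stayed past the threshold after the length correction, but the means moved from −0.35 to −0.17 and from −0.31 to −0.15, so a part played by length cannot be told apart from other causes because less of the difference was left than the bound set for excluding length. Without cortex 1 only 1 of the 3 lists passed, so the ribosomal and oxidative phosphorylation differences may come from that library. In other comparisons the length correction ended 6 calls of these lists, and a difference between the regions themselves stays open.

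The second pattern was that disease-associated microglia genes varied together between libraries of one region (median pairwise correlation 0.58). After the length correction the value was 0.63, at percentile 100 of 10000 random lists (highest 0.28), which argues against length. Handling shared by same-numbered libraries cannot be told apart from other causes: in every region the list mean lay below the region's mean in replicate 1 (−0.85 to −0.29) and above it in replicate 3 (0.09 to 1.09), but replicate 2 ran from −0.80 to 0.76, and the number's share of the variance, 0.59 against a permutation median of 0.18, left p = 0.0833 (exact permutation within regions). Border-associated macrophages among the sorted cells may contribute, since the mean of Lyve1, F13a1, Cd163 and Pf4 correlated with the list at r = 0.63 over the 12 libraries (exact one-sided permutation within regions, 1296 permutations, p = 0.0386; rho = 0.63, p = 0.0394; 1 relation tested), but r was 0.45 without striatum 1 and cortex 3, the libraries farthest from the median of the markers, and 0.17 with the means of the replicate numbers removed, so the relation is not separated from the number. In hippocampus 2 the list was raised by 0.76 while the markers were at −1.27, the TMEM119+ CD45low gate should remove such cells, and no biological explanation was tested, since the pattern lies within regions.

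The third pattern was the absence of counts for well expressed genes in striatum 2. Sequencing depth is argued against, since the other 11 libraries thinned to the same total had a median of 17 such genes at 0 (highest 50). For loss of molecules before amplification, a model of uniform loss fitted to the less expressed genes predicted 6.0 zeros among the 5009 more expressed genes, where 52 were seen. The bound set in advance on this ratio was wrong, because the model takes the profile of the other libraries with sampling error only, and it also failed in 4 of those 11, each with 1 such zero where almost none was predicted. Molecule loss therefore cannot be told apart from other faults of this library, and no biological explanation was tested, since the pattern is in 1 library.

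Other splits of the libraries were counted for each comparison. In the shares of 10 and of 100 below, the real split is itself counted in both numbers. For each of the 6 pairs, 10 of 10 splits gave as many genes as the real one (0, highest other 0), which any split of a count of 0 does, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, 2 of 10 splits gave at least the genes seen in striatum minus cortex (683) and in striatum minus hippocampus (530). In the other pairs 6 to 9 of 10 did. Over the 4 regions and for cerebellum against the mean, 100 of 100 groupings gave as many, but a real count of 0 is matched by any grouping, so these counts decide nothing (highest other 5 and 810). At an unadjusted p under 0.05, 73 of 100 groupings gave at least the 222 genes seen over the 4 regions (highest other 1909) and 94 of 100 at least the 131 seen for cerebellum against the mean (highest other 2744), so chance cannot be excluded. The 810 genes were called with cortex 1, cerebellum 1 and hippocampus 2 in the place of cerebellum, which points to a structure of the samples other than region, although only 3 of 99 drawn groupings called any gene there. In these 3 libraries expression relative to the mean of all libraries fell with transcript length (Spearman rho across genes, which are not independent replicates, −0.60, −0.52 and −0.50, against 0.04 to 0.52 in the others), and after the length correction this split called 89 genes. Among list tests, 17 of 100 groupings gave at least the 40 seen (highest other 56, median 32), so chance cannot be excluded for the list calls.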
